A study of Mus musculus with 9 samples.

How the data were processed

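RNA was measured in 9 libraries of whole cortical tissue from C57Bl/6 mouse embryos at E13.5. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase treatment and made into stranded mRNA libraries. The labels give 3 genotype groups of 3 libraries: Smarca1 +/+ without Cre (WT), Smarca1 −/− without Cre (Smarca1 KO) and Smarca1 −/− carrying 1 Cre allele (DKO). The series' design text names the last group as the Smarca5 and Smarca1 double knockout. The driver of the Cre, the exons removed and the Smarca5 genotype of the other 2 groups are not given in the sources used here.

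The authors deposited 1 table per library of transcripts quantified with Salmon 1.4.0, per the submitters' processing notes, which also name the genome build mm10 and DESeq2, with no role for DESeq2. Each deposited table gives estimated counts per transcript (reads divided among the transcripts they match, not normalised), TPM (transcripts scaled to a fixed total within the library), transcript length and effective length, per the file headers. The estimated counts were used for the tests. The deposited TPM and effective lengths were used only to make length offsets for an alternative fit. The transcript index, the annotation release and the library-type setting are not given in the sources used here, so it is not known whether Salmon's counting used strand.

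Each table held 116546 transcripts. Their identifiers, without version numbers, were matched to GENCODE M21 (GRCm38): 115977 matched and 569 did not, and the unmatched ones held 0.104% to 0.116% of the reads of a library. Counts were summed over the transcripts of each of 35498 genes and rounded to whole numbers. Only 18 of these genes were long non-coding RNA genes. Coordinates are those of GENCODE M21 on GRCm38, counted from 1.

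The sums over genes were 27466046 to 46007527 counts per library. A gene at 0 in a group was given a floor of 3 counts per library. This floor covers counting error only, since the reads carried no molecular identifiers that are known here.

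Differential expression was tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), on all 9 libraries in 1 fit with group means and no covariate. Scaling was by TMM, whose factors lay between 0.991 and 1.02. filterByExpr kept 15773 genes. The quasi-likelihood F test (glmQLFit and glmQLFTest) gave p-values, which were adjusted by the Benjamini-Hochberg method over the 15773 genes of a comparison, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 10.2%. The standard error of a log2 fold change was its size divided by the square root of F. Adjusted p-values of genes in the report are from this test. Levels are TMM-scaled CPM (counts scaled to a fixed library total), given as mean ± SD over the 3 libraries of a group.

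The 3 comparisons were DKO against Smarca1 KO, DKO against WT and Smarca1 KO against WT. Before the data were examined, 22 gene lists were fixed. They were cell type lists (radial glia, intermediate progenitors, projection neurons, Cajal-Retzius cells, ventral interneurons, cortical hem and choroid plexus, diencephalon, blood, endothelium and mural cells, microglia, meninges and mesenchyme), pathway lists (G1/S and replication, G2/M and mitosis, p53 targets, interferon response), complexes (ISWI complex subunits, other remodellers), RNA and tissue handling (immediate early and stress genes, hypoxia and glycolysis) and locus or control classes (imprinted genes, clustered protocadherins, ribosomal proteins). Each was tested with fry, whose directional p asks whether the genes of a list move, on balance, 1 way, and was adjusted over the 22 lists of a comparison. Fry does not compare a list with other genes. Camera with a correlation estimated for each list was the alternative. It compares a list with other genes, so it asks a different question from fry. Values given "with an estimated correlation" are those of camera. A call lost there may be lost through that question and not through the correlation. Counts of called members are over all 15773 genes, and the count with the adjustment made within the list is given as "adjusted over the list alone". A list's score in a library was the mean, over its members, of the log2 CPM difference from the mean of the 9 libraries.

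The genes named were set by a rule fixed before the data were examined. Smarca5 and Smarca1 were always named, and a further gene always named by that rule is not reported here. Then came, per comparison, the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, a symbol that is not a predicted model, and no overlap between the 3 libraries of one group and those of the other. From each list came up to 4 called members with the smallest p or, where none was called, the member with the smallest p. Other genes are said to have been chosen after their values were seen.

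Reads shared between genes were measured as the percent of a gene's distinct 31-mers that occur in another gene of the transcript set. Overlaps of calls were set beside the number for independent lists and beside 20 simulated data sets without effects, since the comparisons share libraries. The libraries of a group were compared in pairs by a chi-square statistic over genes: it was 3.57 to 5.01 per degree of freedom in WT, 11.4 to 22.0 in Smarca1 KO and 8.93 to 22.6 in DKO, so no 2 libraries agreed within sampling noise. The 9 libraries share 1 estimate of the spread although the WT libraries differed less from each other than the mutant ones did.

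The tests were tried on simulated counts with the real means and library sizes, with 98 to 100 changed genes of each fold size among those tested. For DKO against Smarca1 KO (15641 genes), 63.6% of genes changed 1.5-fold and 75.8% of those changed 2-fold were called. The shares were 58.2% and 70.4% for DKO against WT (15615 genes) and 69% and 76.8% for Smarca1 KO against WT (15626 genes). False calls were 9 of 147, 6 of 132 and 8 of 153. In 20 simulated runs of DKO against WT over 15773 genes, a list shifted to 0.75 of its level was called by fry in 20, and unchanged lists in 2 of 420 tests. The simulated genes were drawn independently, each with the same spread in all groups. Real lists had estimated correlations, 0.923 for G2/M and mitosis in DKO against WT, so these rates may not hold for them.

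Alternatives were DESeq2 1.42.0 (with its own filtering in place of filterByExpr), limma-voom, RLE size factors, no low-count filter, a minimum mean of 10 counts, effective-length offsets, a fit of only the 2 groups compared, the replicate number as a block, the log2 of the summed CPM of 4 Y-linked genes as a covariate (the Y-linked covariate), X and Y genes left out, and each library left out in turn. A fit without the third group, and fits without a library, use fewer libraries for the estimate of the spread. The 5 added after seeing the data were protein-coding genes only, GC-content offsets, chromosome 17 between 20 and 45 Mb left out, the 2 libraries highest in meninges and mesenchyme markers left out together, and the ISWI list without Smarca5. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). No library was left out of the main test.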

Results

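Gene expression was measured in the cortex of mouse embryos at E13.5, when radial glia divide and the first cortical neurons form. The genotypes concern the ATPases of the ISWI chromatin remodelling complexes, Smarca1 (SNF2L) and Smarca5 (SNF2H), which slide and space nucleosomes. There were 3 libraries each of wild type (WT), of Smarca1 knockout (Smarca1 KO) and of the double knockout (DKO), which carries a Cre allele on the Smarca1 knockout background. Counts summed over genes were 37910647, 29581173 and 27466046 in Smarca1 KO replicates 1 to 3, 35853215, 30934667 and 46007527 in DKO and 39423035, 28982116 and 30700835 in WT. The labels do not say whether the replicates are separate embryos, so p-values measure the spread between these samples, which may be technical.

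Smarca5 RNA (ENSMUSG00000031715.14, GRCm38 chromosome 8, 80698507 to 80739497) was 84.4, 79.2 and 77.2 CPM in the DKO libraries, against 245.8, 243.1 and 212.2 CPM in Smarca1 KO and 267.4, 270.7 and 262 CPM in WT. It fell in DKO against Smarca1 KO (log2 fold change −1.54, SE 0.061, adjusted p = 2.99e-06) and against WT (log2 fold change −1.73, SE 0.061, adjusted p = 2.05e-06), in the direction that the series' design text gives. Between Smarca1 KO and WT its log2 fold change was −0.19 (SE 0.059, adjusted p = 0.159). Of the 31-mers of Smarca5, 32.8% also occur in other genes. Smarca1 RNA (ENSMUSG00000031099.16, chromosome X, 47809368 to 47892974) was 42.3, 35.3 and 43.8 CPM in Smarca1 KO, 37.9, 38.8 and 38.4 CPM in DKO and 37.8, 36.4 and 37.3 CPM in WT. Its log2 fold change was 0.12 (SE 0.073, adjusted p = 0.378) in Smarca1 KO against WT, 0.046 (SE 0.073, adjusted p = 0.709) in DKO against WT and −0.077 (SE 0.073, adjusted p = 0.644) in DKO against Smarca1 KO. The exons deleted are not given in the sources used here and RNA outside them can persist, so the Smarca1 counts do not check the Smarca1 labels.

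**Figure D1:**
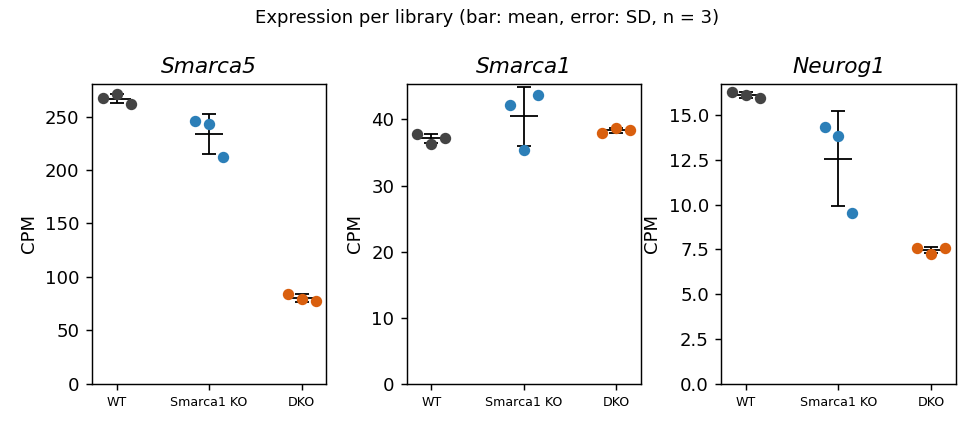
CPM of Smarca5, Smarca1 and Neurog1 in each library (points), by group, with the mean and SD of the 3 libraries. Smarca5 lies at 77.2 to 84.4 CPM in DKO and at 212.2 CPM or more in the other libraries, while the Smarca1 values of Smarca1 KO span those of the other groups.

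The comparison of DKO with Smarca1 KO holds the Smarca1 genotype constant and asks what changes with the Cre and the loss of Smarca5. Over all 9 libraries, the groups took up 0.809 of the variance (R2) of the Y-linked covariate. Differences tied to the Y-linked genes, such as the sex of the samples, therefore cannot be told apart from the group. Ppp1r17 (chromosome 6, 56017497 to 56032689), which encodes an inhibitor of protein phosphatases, rose from 1.27 ± 0.203 CPM to 9.39 ± 1.23 CPM (log2 fold change 2.89, SE 0.22, adjusted p = 0.000203). Itprid1, its neighbour (chromosome 6, 55836895 to 55978735), rose as well (log2 fold change 1.65, SE 0.24, adjusted p = 0.00699). Neurod4, a proneural transcription factor, fell from 7.62 ± 0.928 CPM to 2.58 ± 0.158 CPM (log2 fold change −1.56, SE 0.16, adjusted p = 0.00113), and so did Neurog1, another proneural factor (log2 fold change −0.75, SE 0.14, adjusted p = 0.0174). Members of the beta protocadherins, neuronal adhesion molecules encoded in a cluster on chromosome 18, made up 3 of the 10 largest falls. These were Pcdhb16 at −1.82, Pcdhb21 at −1.62 and Pcdhb8 at −1.50.

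Other large rises were those of Fndc3c1 (2.10), the ammonia transporter gene Rhcg (2.02), the kinase gene Stk26 (1.79), the phospholipase C gene Plcd4 (1.70), the glial adhesion gene Hepacam (1.61), the transcription factor gene Cebpa (1.56) and Sypl2 (1.48), in log2 fold change, with adjusted p between 6.02e-05 and 0.0404. Ppp1r14a, which encodes an inhibitor of myosin phosphatase, fell (log2 fold change −1.75, SE 0.22, adjusted p = 0.00388). Several leading genes share sequence with others and are uncertain. Pgk1-rs7 had 0 counts in all 3 Smarca1 KO libraries, 8.78 CPM in DKO and 7.52 CPM in WT. It was at least 91-fold higher in DKO, against a floor of 3 counts per library, and 100% of its 31-mers occur in other genes. Rps18, a gene of the small ribosomal subunit, fell from 227.5 ± 18.2 CPM to 41.5 ± 2.1 CPM (log2 fold change −2.46, SE 0.076, adjusted p = 5.67e-07) with 22.1% of its 31-mers shared. Its level in WT was 40.1 ± 3.14 CPM. Counts summed over Rps18 and its near-identical copies, a test added later, had a log2 fold change of 0.06 (SE 0.062, adjusted p = 0.676). Xlr3b fell with a log2 fold change of −1.90, adjusted p = 0.0308 and 68.8% of its 31-mers shared, and the zinc finger gene Zfp976 with −1.57, adjusted p = 0.00341 and 34.8% shared. AC149090.1, on an unplaced scaffold, fell (log2 fold change −1.51, SE 0.34, adjusted p = 0.0404) from 166 ± 10.7 CPM to 58.3 ± 4.23 CPM, and stood at 155.4 ± 98.4 CPM in WT.

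Targets of p53 rose as a list. Of 34 measured, 6 rose and 28 were not called (fry adjusted p = 0.00936), and 11 were called adjusted over the list alone. The call was lost in camera (adjusted p = 0.287), which compares the list with other genes, at an estimated correlation of 0.03. Among the 6 were Sesn2, a stress-induced regulator of mTORC1 (log2 fold change 0.92, SE 0.15, adjusted p = 0.00961), the cell cycle inhibitor gene Cdkn1a (0.61, adjusted p = 0.0204), Ccng1 (0.38, adjusted p = 0.0326) and the apoptosome gene Apaf1 (0.24, adjusted p = 0.0199). Immediate early and stress genes rose as a list, with 2 of 19 called (fry adjusted p = 0.00936) and 8 adjusted over the list alone. The list's median log2 fold change was 0.081 and its mean 0.291, so the rise was uneven over its members. Camera gave adjusted p = 0.287 at an estimated correlation of −0.045. The 2 were the heat shock genes Hspa1b (1.19) and Hspa1a (1.33), which share 68% and 65.4% of their 31-mers with other genes, so the share of each is uncertain. Interferon response genes rose as a list, with 2 of 16 called (fry adjusted p = 0.0293), 4 adjusted over the list alone and adjusted p = 0.287 with an estimated correlation. These were Ifit2 (log2 fold change 0.88, SE 0.12, adjusted p = 0.0055) and Ifit3 (1.67, adjusted p = 0.0441), the latter under 1 CPM in every group with 61.8% of its 31-mers shared. The interferon list's score was 0.43 in DKO replicate 1, 0.080 and 0.27 in DKO replicates 2 and 3, and DKO replicate 1 also had a meninges and mesenchyme marker score of 0.66. That marker score was −0.47 in DKO replicate 3, and 0.69 in Smarca1 KO replicate 1, where the interferon score was 0.07. The interferon call was lost without any 1 of Smarca1 KO replicates 2 and 3, DKO replicates 1 and 3 and each WT replicate (adjusted p between 0.0685 and 0.116).

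Clustered protocadherins fell as a list. Of 55 measured, 22 fell, 3 rose and 30 were not called (fry adjusted p = 0.0293), and 34 were called adjusted over the list alone. The call was lost at adjusted p = 0.287 with an estimated correlation, and without any 1 library except Smarca1 KO replicate 2 (adjusted p between 0.0508 and 0.0816). It was also lost with the replicate number as a block (adjusted p = 0.0727). The falls were mostly in the beta cluster, where 18 of 21 members fell, against 1 of 12 in the alpha and 3 of 22 in the gamma cluster. Pcdhb19 (log2 fold change −1.24, SE 0.10, adjusted p = 0.000343), Pcdhb17 (−1.47, adjusted p = 0.000451), Pcdhb11 (−1.48, adjusted p = 0.00274) and Pcdhb20 (−1.25, adjusted p = 0.00304) had the smallest p. Counts summed over the beta cluster were 72.6 ± 4.48 CPM in WT, 122.5 ± 14.5 CPM in Smarca1 KO and 50.7 ± 8.0 CPM in DKO.

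**Figure D2:**
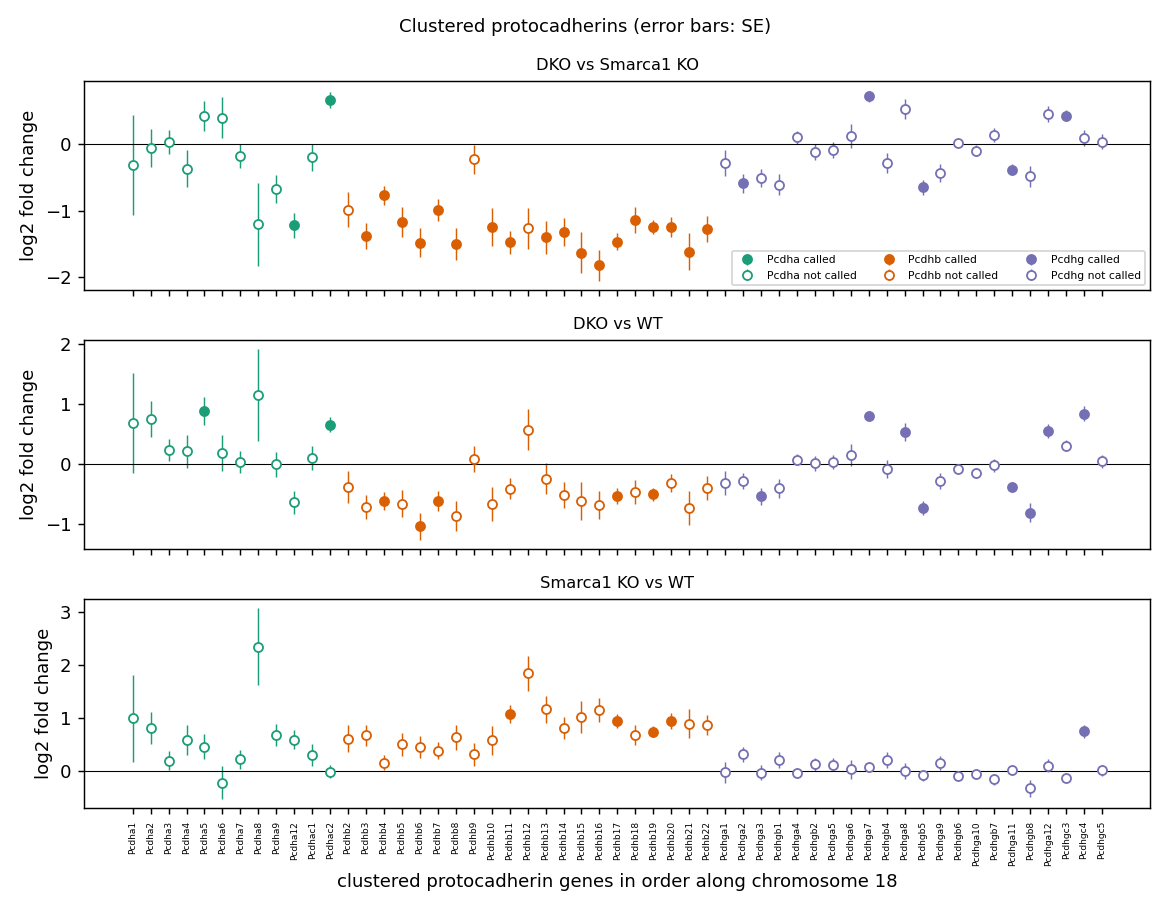
Log2 fold change with SE of each tested clustered protocadherin, in order along chromosome 18, in the 3 comparisons (panels), coloured by cluster, with filled points for called genes. In DKO against Smarca1 KO, 18 of the 21 beta genes are called lower, and in Smarca1 KO against WT 4 are called higher.

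The neural cell type lists were not called in DKO against Smarca1 KO. Of 17 intermediate progenitor genes 3 fell (fry adjusted p = 0.109, 4 adjusted over the list alone), namely Neurod4, Neurog1 and Mfap4 (−0.45). Of 26 radial glia genes 2 fell (fry adjusted p = 0.68, 3 adjusted over the list alone), the glycolytic gene Aldoc (log2 fold change −0.85, SE 0.066, adjusted p = 0.000204) and the dorsal transcription factor gene Emx1 (−0.36, adjusted p = 0.0408). The radial glia median was 0.015, its mean −0.068 and its test pointed down. Of 28 projection neuron genes Fezf2, a factor of deep layer neurons, fell (−0.51, adjusted p = 0.0055) and Lmo3 rose (0.40, adjusted p = 0.0473), with fry adjusted p = 0.685, 3 adjusted over the list alone, a median of 0.004, a mean of −0.079 and a test that pointed down. Sp8 (0.38) rose among 27 ventral interneuron genes (fry adjusted p = 0.109, 1 adjusted over the list alone) and Wnt5a (0.53) among 23 genes of cortical hem and choroid plexus (fry adjusted p = 0.666, 1 adjusted over the list alone). Of 20 microglia genes the receptor genes Cx3cr1 (0.66, adjusted p = 0.00807) and Trem2 (0.81, adjusted p = 0.0481) rose (fry adjusted p = 0.109, 4 adjusted over the list alone). The microglia score was 0.47, 0.050 and 0.26 in DKO replicates 1 to 3. The microglia list was called up without DKO replicate 2 (adjusted p = 0.0462), and the intermediate progenitor list down without Smarca1 KO replicate 3 (adjusted p = 0.0147).

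Among the other lists, Smarca5 was the called member of the 13 ISWI complex genes (fry adjusted p = 0.0683, 2 adjusted over the list alone). Without Smarca5, the gene removed, the list had fry adjusted p = 0.755. Without Smarca1 KO replicate 3 the list passed with Smarca5 (adjusted p = 0.0143) but not without it (adjusted p = 0.252). Of 25 hypoxia and glycolysis genes, the glucose transporter gene Slc2a3 rose (0.56) and Bhlhe40 (−0.52) and Ddit4 (−0.24) fell (fry adjusted p = 0.136, 3 adjusted over the list alone). The cyclin gene Ccnb2 fell (−0.44, adjusted p = 0.0394) among 37 genes of G2/M and mitosis (fry adjusted p = 0.685, 0 adjusted over the list alone). Rps18 fell among 77 ribosomal protein genes (fry adjusted p = 0.753, 1 adjusted over the list alone). In 8 lists with 173 members edgeR called no member, while 23 members had an unadjusted p under 0.05 and DESeq2 called 5. Their fry adjusted p was 0.266 for Cajal-Retzius cells (Trp73 at 0.43), 0.685 for diencephalon (Olig3 at 1.55), 0.685 for blood (Hbb-bs at −0.37, with 54.4% of its 31-mers shared) and 0.755 for endothelium and mural cells (Slco1c1 at −0.44). It was 0.685 for G1/S and replication (Mcm6 at 0.27), 0.68 for other remodellers (Chd4 at −0.12) and 0.713 for imprinted genes (Ppp1r9a at −0.24). For meninges and mesenchyme (Fbln1 at 0.17) it was 0.955, with a median of 0.03, a mean of −0.008 and a test that pointed up. Of these 8 lists, Cajal-Retzius cells had 1 member called adjusted over the list alone and the others 0.

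**Figure D3:**
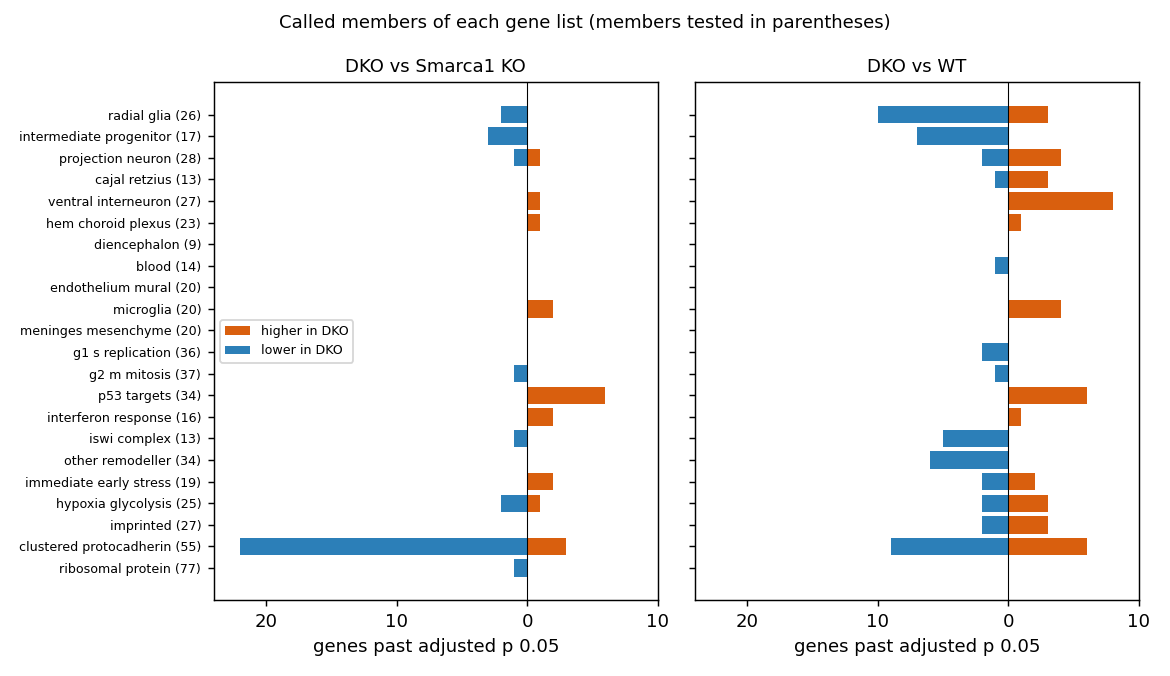
Number of called members of each gene list (horizontal axis, higher in DKO to the right and lower to the left), in DKO against Smarca1 KO and DKO against WT, with the members tested in parentheses. Clustered protocadherins have 22 members lower against Smarca1 KO, and radial glia have 10 lower against WT.

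In all, 273 genes rose and 419 fell in DKO against Smarca1 KO, 692 of 15773 tested (4.39%). Their median absolute log2 fold change was 0.48. There were 62 rises and 76 falls over 2-fold, and 2905 genes at an unadjusted p under 0.05. The rises and falls were 68 and 113 when only these 2 groups were fitted, 148 and 250 without Smarca1 KO replicate 1 and DKO replicate 1 (the libraries highest in meninges markers), 146 and 243 with effective-length offsets, 471 and 657 with DESeq2 and 3 and 5 with a Y-linked covariate that follows the groups. They were 127 and 227 without Smarca1 KO replicate 2, 100 and 186 without DKO replicate 2, 105 and 183 without DKO replicate 3. They were 152 and 265, 151 and 271, and 149 and 269 without WT replicates 1, 2 and 3, and the falls were 255 without DKO replicate 1. A split that mixed the genotypes, Smarca1 KO replicates 1 and 2 with DKO replicate 1 against the rest of these 2 groups, called 961 genes.

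DKO against WT compares the double knockout, which also carries the Cre, with the wild type. The limit set by the Y-linked genes holds here as well. Ppp1r17 (log2 fold change 2.82, SE 0.22, adjusted p = 0.000353) and its neighbour Itprid1 (log2 fold change 2.38, SE 0.26, adjusted p = 0.00144) rose here too. Chrna3, which encodes a subunit of nicotinic acetylcholine receptors, rose from 2.59 ± 0.247 CPM to 10.1 ± 0.854 CPM (log2 fold change 1.96, SE 0.16, adjusted p = 0.000497). Neurod4 fell to 2.58 ± 0.158 CPM from 7.4 ± 1.26 CPM (log2 fold change −1.52, SE 0.16, adjusted p = 0.00124). Slc15a2, which encodes a peptide transporter, fell from 77.2 ± 10.3 CPM to 25.6 ± 10.6 CPM (log2 fold change −1.60, SE 0.33, adjusted p = 0.0177), and Ppp1r14a fell as well (−1.97, adjusted p = 0.0018).

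Hepacam (1.91), Plcd4 (1.83), Frmpd4 (1.72), the chemokine gene Ccl28 (1.70), the metallothionein gene Mt2 (1.66), the urea transporter gene Slc14a1 (1.66) and Mybpc1 (1.61) completed the 10 largest rises, with adjusted p between 4.82e-05 and 0.0465. Shcbp1 (−1.35), Emid1 (−1.28), AC149090.1 (−1.42) and, with shared sequence and so uncertain, Xlr3b (−1.84), Zfp976 (−1.54) and Vmn2r-ps54 (−1.25, 27.2% of its 31-mers shared) were among the 10 largest falls, with adjusted p between 0.000234 and 0.0342. AC149090.1 was at 268.2, 110.5 and 87.5 CPM in WT replicates 1 to 3. Its log2 fold change was −0.767 (adjusted p = 0.0146) without WT replicate 1, and its call was lost without DKO replicate 1, 2 or 3 (adjusted p = 0.0583, 0.0854 and 0.086).

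Progenitor lists fell in DKO against WT. The radial glia mean log2 fold change was −0.261 here and −0.193 in Smarca1 KO against WT. In the latter comparison the list was not called (fry adjusted p = 0.0893), and both comparisons share the WT libraries. The radial glia score was 0.011, 0.031 and −0.18 in Smarca1 KO replicates 1 to 3, so replicate 3 weighs on that mean. In WT replicates 1 to 3 it was 0.125, 0.179 and 0.156. The intermediate progenitor mean was −0.349 here and −0.113 in Smarca1 KO against WT. Of 17 intermediate progenitor genes 7 fell and 10 were not called (fry adjusted p = 0.0222, 10 adjusted over the list alone), and the call was lost at adjusted p = 0.346 with an estimated correlation. They included the proneural genes Neurog1 (log2 fold change −1.11, SE 0.14, adjusted p = 0.00264) and Neurog2, from 237.7 ± 4.41 CPM to 162.1 ± 9.38 CPM (log2 fold change −0.55, SE 0.094, adjusted p = 0.00926), and Mfap4 (−0.51, adjusted p = 0.0134). Of 26 radial glia genes 10 fell, 3 rose and 13 were not called (fry adjusted p = 0.0222, 21 adjusted over the list alone), and that call was lost at adjusted p = 0.346 with an estimated correlation. Aldoc (log2 fold change −0.94, SE 0.066, adjusted p = 0.000196), Emx1 (−0.62, adjusted p = 0.00335) and the cortical selector gene Lhx2 (−0.58, adjusted p = 0.00553) fell, and the glutamate transporter gene Slc1a3 rose (0.43, adjusted p = 0.00345). The intermediate progenitor call was lost without any 1 DKO replicate or without WT replicate 1 or 2 (adjusted p between 0.0561 and 0.0882). The radial glia call was lost without any 1 DKO or WT replicate (adjusted p between 0.0515 and 0.0893).

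Ventral interneuron genes rose as a list, with 8 of 27 called (fry adjusted p = 0.0274, 13 adjusted over the list alone) and adjusted p = 0.41 with an estimated correlation. Six3 (log2 fold change 0.44, SE 0.076, adjusted p = 0.0097), Maf (0.48, adjusted p = 0.0182), Dlx5 (0.30, adjusted p = 0.0232), a homeobox gene of GABAergic neurons, and Slc32a1 (0.36, adjusted p = 0.0296), the vesicular GABA transporter gene, were among the 8. Microglia genes rose, with 4 of 20 called (fry adjusted p = 0.0274, 5 adjusted over the list alone) and adjusted p = 0.41 with an estimated correlation. The complement genes C1qa (log2 fold change 1.15, SE 0.18, adjusted p = 0.00636) and C1qc (1.08, adjusted p = 0.00594), Cx3cr1 (0.77, adjusted p = 0.00339) and Trem2 (0.92, adjusted p = 0.0194) made up the 4. The microglia score was highest in DKO replicate 1 (0.47), whose meninges and mesenchyme score was 0.66. The 2 scores did not go together in all libraries. In DKO replicate 3 the microglia score was 0.26 and the meninges and mesenchyme score −0.47. In Smarca1 KO replicate 1 they were 0.22 and 0.69. The interneuron call was lost without Smarca1 KO replicate 1, DKO replicate 2 or 3, or WT replicate 1 or 2 (adjusted p between 0.0511 and 0.0965). It was also lost with the replicate number as a block (adjusted p = 0.0513). The microglia call was lost without DKO replicate 1 or 3 or any 1 WT replicate (adjusted p between 0.0715 and 0.0909).

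Targets of p53 rose in DKO against WT too, with 6 of 34 called (fry adjusted p = 0.0156, 9 adjusted over the list alone) and adjusted p = 0.346 with an estimated correlation. Sesn2 (0.79), Cdkn1a (0.60), Ccng1 (0.41) and Perp (1.10), with adjusted p between 0.0119 and 0.0157, were among the 6. ISWI complex genes fell, with 5 of 13 called (fry adjusted p = 0.0123, 6 adjusted over the list alone) and adjusted p = 0.346 with an estimated correlation. Without Smarca5, the gene removed, 4 of 12 were called with fry adjusted p = 0.033 and adjusted p = 0.497 with an estimated correlation. The mean log2 fold change of these 12 was −0.143, and −0.124 in Smarca1 KO against WT, so most of their mean fall was present there too. These 12 were not called there as a list (fry adjusted p = 0.0893), and both comparisons share the WT libraries. This list's call was lost without any 1 library except Smarca1 KO replicates 2 and 3 (adjusted p between 0.0517 and 0.11). Apart from Smarca5, the partner subunit genes Cecr2 (log2 fold change −0.42, SE 0.079, adjusted p = 0.0129), Rsf1 (−0.17, adjusted p = 0.0247) and Baz1b (−0.22, adjusted p = 0.0289) fell. Genes of other remodellers fell, with 6 of 34 called (fry adjusted p = 0.0222, 11 adjusted over the list alone) and adjusted p = 0.476 with an estimated correlation. Among them were Chd4, the NuRD ATPase gene (log2 fold change −0.31, SE 0.036, adjusted p = 0.00211), Smarcc1 (−0.26, adjusted p = 0.00685), Mta1 (−0.23, adjusted p = 0.0193) and Chd2 (−0.20, adjusted p = 0.0269). The mean of the other remodellers was −0.066 here and −0.046 in Smarca1 KO against WT. The p53 call was lost without DKO replicate 3 or WT replicate 1 or 2 (adjusted p between 0.0559 and 0.067) and the ISWI call without DKO replicate 3 or WT replicate 1 (adjusted p = 0.0559 and 0.0538). That of the other remodellers was lost without DKO replicate 1 or 3 or WT replicate 1 or 2 (adjusted p between 0.067 and 0.0882). With the replicate number as a block it was lost too (adjusted p = 0.0505).

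The remaining lists were not called in DKO against WT, with members that went both ways in several. Of 28 projection neuron genes 4 rose and 2 fell (fry adjusted p = 0.491, 13 adjusted over the list alone), Lmo3 (0.55) and Stmn2 (0.44) rising and Fezf2 (−0.45) and Slc17a7 (−0.55) falling. Of 13 Cajal-Retzius genes 3 rose, namely Calb2 (1.07), Ndnf (0.65) and Trp73 (0.39), and Nhlh2 fell (−0.25), with fry adjusted p = 0.157, 5 adjusted over the list alone, and adjusted p = 0.00703 without Smarca1 KO replicate 2. Of 55 clustered protocadherins 6 rose and 9 fell (fry adjusted p = 0.491, 21 adjusted over the list alone). Pcdhga7 (0.80), Pcdhgc4 (0.84) and Pcdhac2 (0.66) rose and Pcdhgb5 (−0.73) fell, each uncertain because 37.4% to 48.4% of their 31-mers are shared. Of 19 immediate early and stress genes 2 rose, Hspa1a (1.81) and Ier3 (0.64), and 2 fell, Jun (−0.38) and Ier2 (−0.42), with fry adjusted p = 0.199, 10 adjusted over the list alone, and adjusted p = 0.0293 without Smarca1 KO replicate 1. Of 25 hypoxia and glycolysis genes 3 rose, among them Slc2a3 (0.82) and Ankrd37 (0.73), and Bhlhe40 (−0.73) and Ddit4 (−0.22) fell (fry adjusted p = 0.578, 6 adjusted over the list alone). Of 27 imprinted genes 3 rose, among them Nap1l5 (0.91) and Nnat (0.31), and Igf2r (−0.27) and Plagl1 (−0.35) fell (fry adjusted p = 0.767, 5 adjusted over the list alone).

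Single members were called in other lists. Ifit2 (0.70) rose among 16 interferon response genes (fry adjusted p = 0.0625, 1 adjusted over the list alone, adjusted p = 0.0434 with effective-length offsets and 0.0384 with the replicate number as a block), and the transthyretin gene Ttr (0.90) among 23 hem and choroid plexus genes (fry adjusted p = 0.5, 0 adjusted over the list alone). Ccnb2 (−0.68) fell among 37 genes of G2/M and mitosis (fry adjusted p = 0.453, 1 adjusted over the list alone), and the haemoglobin gene Hba-a1 (−0.83, 75.5% of its 31-mers shared) among 14 blood genes (fry adjusted p = 0.26, 0 adjusted over the list alone). E2f8 (−0.34) and Tyms (−0.38) fell among 36 genes of G1/S and replication (fry adjusted p = 0.253, 0 adjusted over the list alone, and adjusted p = 0.0419 without Smarca1 KO replicate 3). In the 4 lists with no member called by edgeR, 5 of 126 members had an unadjusted p under 0.05 and DESeq2 called 2. Their fry adjusted p was 0.509 for diencephalon (Olig3 at 1.29), 0.732 for endothelium and mural cells (Eng at −0.30), 0.783 for meninges and mesenchyme (Prrx1 at −0.52) and 0.611 for ribosomal proteins (Rpl38 at 0.19), with 0 adjusted over the list alone in each.

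**Figure D4:**
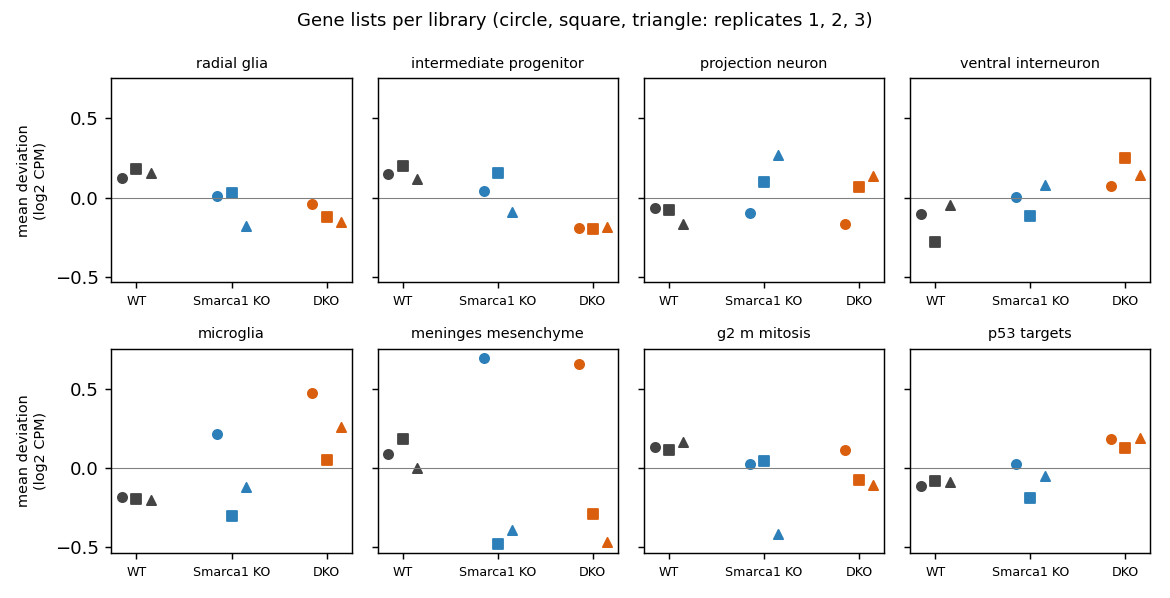
Mean deviation of the members of 8 gene lists from the mean of the 9 libraries (log2 CPM), per library and group, with replicates 1, 2 and 3 as circle, square and triangle. Meninges and mesenchyme markers stand at 0.69 in Smarca1 KO replicate 1 and 0.66 in DKO replicate 1 and at −0.29 or lower in the other mutant libraries.

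Between DKO and WT 885 genes rose and 1002 fell, 1887 of 15773 tested (11.96%). Their median absolute log2 fold change was 0.39. There were 156 rises and 68 falls over 2-fold, and 4890 genes at an unadjusted p under 0.05. Rises and falls numbered 1711 and 1732 when only these 2 groups were fitted and 1 and 3 with the Y-linked covariate. The rises were 1345 with DESeq2, 587 with effective-length offsets and 1439 without the 2 libraries highest in meninges markers. Rises and falls were 1512 and 1666 without Smarca1 KO replicate 3, 294 and 421 without DKO replicate 2, 224 and 319 without DKO replicate 3. They were 169 and 281, 202 and 339, and 191 and 330 without WT replicates 1, 2 and 3.

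Smarca1 KO against WT asks what the loss of Smarca1 alone changes. It called 53 genes. Rps18 (chromosome 17, 33951999 to 33956001) rose from 40.1 ± 3.14 CPM to 227.5 ± 18.2 CPM (log2 fold change 2.50, SE 0.076, adjusted p = 4.98e-07), uncertain for its shared sequence. Members of the beta protocadherins, which were lower in DKO than in Smarca1 KO, rose in Smarca1 KO against WT in 4 of 21 cases. These were Pcdhb17 (log2 fold change 0.94, SE 0.13, adjusted p = 0.0176), Pcdhb11 (1.07, adjusted p = 0.0387), Pcdhb20 (0.94, adjusted p = 0.0372) and Pcdhb19 (0.74, adjusted p = 0.0215). Hccs (chromosome X, 169250193 to 169320372), which encodes holocytochrome c synthase, rose from 30.5 ± 1.24 CPM to 56.7 ± 4.44 CPM (log2 fold change 0.89, SE 0.063, adjusted p = 0.000321). Msl3 (0.86, adjusted p = 0.00267) and BC022960 (1.36, adjusted p = 0.00516), also on the distal X chromosome, rose too.

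The other rises among the 10 largest were H2-T23 (log2 fold change 1.87, SE 0.18, adjusted p = 0.00265) and Pcdhgc4 (0.75, adjusted p = 0.0422). Pgk1-rs7 was at least 77.9-fold lower than in WT, against the floor of 3 counts per library, and its sequence is shared. Classical class I histocompatibility genes H2-K1 (−0.72, adjusted p = 0.0153) and H2-D1 (−0.50, adjusted p = 0.0225) fell. With H2-T23 they share 22.8%, 26.7% and 24.4% of their 31-mers with other genes. Vmn1r43 (−1.19), the splicing factor gene Rbm20 (−0.88), Arhgap4 (−0.78), Epop (−0.47), Zfp868 (−0.46), the potassium channel gene Kcnn1 (−0.44) and Cad (−0.40), a gene of pyrimidine synthesis, fell with adjusted p between 0.000919 and 0.0425. The receptor gene Notch1 fell (log2 fold change −0.31, SE 0.050, adjusted p = 0.0387).

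No list passed fry between Smarca1 KO and WT, where 5 lists had an unadjusted p under 0.05 and camera with an estimated correlation called 0. The lowest adjusted p were 0.0865 for immediate early and stress genes (Jun at −0.24, 3 adjusted over the list alone). They were 0.0893 for radial glia (1 of 26 fell, Notch1, and 19 adjusted over the list alone), ISWI complex genes (Baz1b at −0.20, 4 adjusted over the list alone), other remodellers (Smarcc1 at −0.24, 8 adjusted over the list alone) and clustered protocadherins (5 of 55 rose, 17 adjusted over the list alone). G1/S and replication genes had fry adjusted p = 0.185 (Chaf1a at −0.40), with 19 of 36 called adjusted over the list alone. The list score of these genes was −0.40 in Smarca1 KO replicate 3, against −0.011 and 0.047 in replicates 1 and 2. Genes of G2/M and mitosis had fry adjusted p = 0.301 (Cdc25c at −0.35), intermediate progenitors 0.319 (Dll1 at −0.27), projection neurons 0.359 (Stmn2 at 0.45, 1 adjusted over the list alone) and hypoxia and glycolysis 0.359 (Hk2 at −0.38). Rps18 was the called member of 77 ribosomal protein genes (fry adjusted p = 0.502, 3 adjusted over the list alone). Without Smarca1 KO replicate 2, fry called 6 lists, with adjusted p = 0.0426 for radial glia, intermediate progenitors and immediate early and stress genes (down) and Cajal-Retzius cells (up), and 0.0447 for ISWI complex genes and other remodellers (down). Immediate early and stress genes were also called down without Smarca1 KO replicate 1 (0.00989) or 3 (0.0331), DKO replicate 1 (0.00784) or WT replicate 3 (0.0467).

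In the 19 lists without a called member, 123 of 432 members had an unadjusted p under 0.05 in edgeR and DESeq2 called 33. The fry adjusted p was 0.502 for ventral interneurons (Isl1 at 0.24), for microglia (C1qc at 0.43) and for interferon response (Ifit3 at −0.79, under 1 CPM). It was 0.578 for blood (Hba-x at −0.81) and for imprinted genes (Nap1l5 at 0.79), 0.822 for Cajal-Retzius cells (Calb2 at 0.67) and 0.905 for meninges and mesenchyme (Fbln1 at −0.36). It was 0.956 for diencephalon (Wnt3 at 0.70), endothelium and mural cells (Slco1c1 at 0.49), hem and choroid plexus (Ttr at 0.56, median −0.041, mean 0.003, test down) and p53 targets (Apaf1 at −0.17, median 0.024, mean 0.043, test down). The lists given without a count adjusted over the list alone had 0 members called that way by edgeR.

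In Smarca1 KO against WT 22 genes rose and 31 fell, 53 of 15773 tested (0.34%). Their median absolute log2 fold change was 0.58. There were 7 rises and 7 falls over 2-fold, and 2978 genes at an unadjusted p under 0.05. Rises and falls were 304 and 303 without Smarca1 KO replicate 1 and DKO replicate 1, which were highest in meninges markers, 252 and 449 with DESeq2 and 36 and 54 without a low-count filter. They were 14 and 17 without Smarca1 KO replicate 3, and 11 and 8, 7 and 7, and 11 and 10 without WT replicates 1, 2 and 3, and the falls were 20 without DKO replicate 2. With the replicate number as a block, rises and falls were 14 and 15.

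Of the 692 genes called in DKO against Smarca1 KO, 502 were called in the same direction in DKO against WT, 185 up and 317 down, 1 was called in the opposite direction and 189 were not called. Ppp1r17, Itprid1, Plcd4 and Hepacam were among those up, and Smarca5, Neurod4, Neurog1, Aldoc and Emx1 among those down. Independent lists would share 15.3 up and 26.6 down, and 20 simulated sets without effects shared a mean of 0.05 and at most 1. DKO against WT and Smarca1 KO against WT shared 28 genes, 12 up and 16 down, with 4 in opposite directions. Independent lists would share 1.2 and 2, and simulated sets shared a mean of 0.05 and at most 1. Hccs, Msl3 and BC022960 were among the 12, and Vmn1r43 among the 16. The simulated sets leave out the effects and so make few calls, and independent lists leave out the shared libraries, so neither is the overlap to be expected here. Part of either excess may come from the shared DKO or WT libraries, which are too few to split. Of the genes called in both DKO against Smarca1 KO and Smarca1 KO against WT, 24 went in opposite directions and 3 in the same. Independent lists would hold 1.1 in opposite directions, simulated sets, with the same limit, held a mean of 0 and at most 0, and part of the excess may come from the shared Smarca1 KO libraries. Rps18, Pcdhb17 and Pcdhb19 were among the 24. The overlap of 502 genes was 774 with DESeq2. That of 28 genes was 424 with DESeq2 and 16 with the replicate number as a block.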

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

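Of the alternatives, 5 were chosen after seeing the data: protein-coding genes only, GC-content offsets, chromosome 17 between 20 and 45 Mb left out, the 2 libraries highest in meninges markers left out, and the ISWI list without Smarca5. Smarca5 kept its fall in every alternative, from −1.61 to −1.37 against Smarca1 KO and from −1.77 to −1.56 against WT in log2 fold change, and no library's omission moved it by over 1.5 times. Smarca1 in DKO against WT changed sign, from 0.046 to −0.047 (adjusted p = 0.984), with the Y-linked covariate, passing no test either way. Without 1 library at a time its log2 fold change was 0.027 to 0.055, and 0.065 to 0.208 in Smarca1 KO against WT.

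Counts of called genes moved most. For DKO against Smarca1 KO, 273 rises and 419 falls became 471 and 657 with DESeq2 (690 of the 692 genes called the same way), 146 and 243 with effective-length offsets (365 shared), 68 and 113 with only the 2 groups fitted (180 shared), 3 and 5 with the Y-linked covariate and 148 and 250 without the 2 libraries highest in meninges markers (324 shared). For DKO against WT, 885 rises became 1345 with DESeq2, 587 with effective-length offsets and 1439 without those 2 libraries. The 885 rises and 1002 falls became 1711 and 1732 with only the 2 groups fitted and 1 and 3 with the Y-linked covariate. For Smarca1 KO against WT, 22 rises and 31 falls became 252 and 449 with DESeq2, 36 and 54 without a low-count filter and 304 and 303 without those 2 libraries (53 of 53 shared). The overlap of 502 genes was 774 with DESeq2, and that of 28 genes 424. The cause was not tested. Some of these fits use fewer libraries. With only the 2 groups fitted, calls fell in DKO against Smarca1 KO and rose in DKO against WT. Fewer libraries alone do not account for moves both ways. The main fit shares 1 spread over all 9 libraries, though WT libraries differed less from each other than the mutant ones did. That spread may therefore be too small for DKO against Smarca1 KO, and its calls too many. The Y-linked covariate was planned only for groups that do not share its variation. It was run although the groups took up 0.809 of its variance (R2), so it can remove group differences too. For the same reason, differences tied to the Y-linked genes, such as the sex of the samples, cannot be told apart from the group. Whether they account for calls in the main fit was not tested. In Smarca1 KO against WT this covariate gave 15 and 32 calls (41 of 53 shared). Apart from the replicate block, the other alternatives kept the gene counts within 1.5 times.

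Without 1 library at a time, rises ranged from 100 to 344 and falls from 183 to 451 in DKO against Smarca1 KO, lowest without DKO replicates 2 and 3. In DKO against WT they ranged from 169 to 1512 and 281 to 1666, lowest without WT replicate 1 and highest without Smarca1 KO replicate 3, and in Smarca1 KO against WT from 7 to 32 and 7 to 41, lowest without WT replicate 2. Of 3219 values of named called genes, 2616 stayed called in the same direction, 603 were no longer called (122 of them with the Y-linked covariate) and 0 changed sign.

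Pairing of the samples by replicate number was not shown, though so few libraries cannot exclude it. The correlation of deviations between same-numbered libraries of Smarca1 KO and DKO was 0.35, −0.035 and 0.106, and those with WT lay between −0.063 and 0.033. Libraries correlated best with their own number in 3 of 6 cases for WT and Smarca1 KO, 0 of 6 for WT and DKO and 2 of 6 for Smarca1 KO and DKO. With the replicate number as a block, calls were 200 and 329 in DKO against Smarca1 KO, 807 and 938 in DKO against WT and 14 and 15 in Smarca1 KO against WT, and the overlaps 393 and 16. Of the lists, clustered protocadherins in DKO against Smarca1 KO (0.0727) and ventral interneurons (0.0513) and other remodellers (0.0505) in DKO against WT were then not called by fry. Interferon response genes in DKO against WT were then called (0.0384).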

Other observations

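The gene groups and single genes of this part were chosen after their values were seen, through 277 groups of genes that share a symbol stem, each tested for an excess of calls in 3 comparisons and both directions (one-sided Fisher's exact test, adjusted within a comparison and direction). All Fisher's exact tests of this part count genes as independent, though the genes come from the same 9 libraries. Their p-values therefore do not measure the spread between samples. The tests chosen after the result was seen were the summed counts of Rps18 and its copies, the ratio of the genes near Rps18, the summed beta protocadherins, the calls on chromosomes 8 and X, and both tests of the loss of Smarca5. The bound for the ratio (a median under 0.25) was made stricter after its values were seen, then put back with the condition that the median lies below 0.5 by more than the SD. In DKO against WT, 16 of 71 genes with the symbol stem Atp rose (adjusted p = 0.000406). Among the 16 were the subunit genes of the vacuolar proton pump Atp6v0e2 at 0.40 (SE 0.056, adjusted p = 0.00404), Atp6v0c at 0.38 (SE 0.072, adjusted p = 0.0141) and Atp6v1a at 0.24 (SE 0.043, adjusted p = 0.00977) in log2 fold change. Of 17 histone lysine demethylase genes (Kdm), 6 fell (adjusted p = 0.0403), Kdm3b at −0.52 (SE 0.047, adjusted p = 0.000627). Of 12 zinc finger genes with the stem Zkscan, 7 fell (adjusted p = 0.000338).

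In DKO against Smarca1 KO, 6 of 33 genes with the stem H rose (adjusted p = 0.00527). The stem mixes histone genes, H1f0 at 0.37 (SE 0.069, adjusted p = 0.0186) and H3f3b at 0.35 (SE 0.039, adjusted p = 0.00219), with class I histocompatibility genes, H2-D1 at 0.996 (SE 0.070, adjusted p = 0.000147) and H2-K1 at 1.14 (SE 0.093, adjusted p = 0.000272). Other genes of the stem went the other way, among them H2-T22 at −3.259 and H2-T23 at −1.155. H2-K1, H2-D1 and H2-T23 share sequence with other genes. On the distal X chromosome, Prps2 (167346322 to 167382749), an enzyme gene of nucleotide synthesis, was higher than in WT in Smarca1 KO, 0.66 (SE 0.059, adjusted p = 0.00163), and in DKO, 0.83 (SE 0.059, adjusted p = 0.000196). Its neighbours behaved likewise: Msl3 stood at 0.86 (SE 0.085, adjusted p = 0.00267) and 0.80 (SE 0.084, adjusted p = 0.00132), Hccs at 0.89 (SE 0.063, adjusted p = 0.000321) and 0.86 (SE 0.062, adjusted p = 0.000212), and BC022960 at 1.36 (SE 0.15, adjusted p = 0.00516) and 1.54 (SE 0.15, adjusted p = 0.00086). All 4 were called in both mutant groups. Frmpd4 (167471309 to 168577231), which lies between Prps2 and Msl3, was called higher in DKO against WT. It stood at 1.14 ± 0.09 CPM in WT, 3.26 ± 1.18 CPM in Smarca1 KO and 3.76 ± 0.40 CPM in DKO.

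Of the 10 splits of the 6 DKO and Smarca1 KO libraries into 3 and 3, 2 gave at least 692 called genes, the real one and 1 that set Smarca1 KO replicates 1 and 2 with DKO replicate 1 against the rest (961). That split points to a structure of the samples. For DKO against WT, 1 of 10 splits, the real one, gave 1887, and the highest other 1. For Smarca1 KO against WT it was again 1 of 10, with 53 and 1. So few splits cannot give a share under 0.05. Within 10 Mb of Smarca5, 7 of 178 other genes were called in DKO against Smarca1 KO (3.93%, against 4.39% elsewhere; two-sided Fisher's exact test, p = 1). Chromosome 8, which carries Smarca5, held 42 of the 692 calls, so linkage to Smarca5 as the whole cause is argued against, while how far linked sequence extends was not measured. Within 10 Mb of Smarca1, 0 of 61 genes were called in Smarca1 KO against WT by edgeR, where 0.2 would match the rest (two-sided Fisher's exact test, p = 1), too few to show an excess near the gene. The X chromosome, which carries Smarca1, held 7 of the 53 calls, so linkage to Smarca1 as the whole cause is argued against too.

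Rps18 rose in Smarca1 KO against WT while its near-identical copies Gm10260, at −1.14 (SE 0.050, adjusted p = 8.97e-06), and Gm11361, at −1.38 (SE 0.10, adjusted p = 0.000384), fell. Counts summed over Rps18 and the 3 genes with at least 50% of their 31-mers in it had a log2 fold change of −0.032 (SE 0.062, adjusted p = 0.819), so reads divided differently among the copies may account for the change of Rps18. The copies were first defined by the share of Rps18 they hold, which returned Rps18 alone, and the definition was changed before the sum was computed. A loss of Smarca1 acting alike with and without Smarca5 needs like changes in both mutant groups. It was weighed on the 6 called genes within 10 Mb as a set, Rps18 among them. Their ratio of DKO to Smarca1 KO changes against WT had a median of −0.083 (SD 0.562, and a median of −0.184 without Rps18). The ratios ran from −0.993 for H2-D1 to 0.383 for H2-T23 and 0.458 for 2310061I04Rik. The median met a bound that was reset after the values were seen. The genes were also chosen as called in Smarca1 KO against WT, which can lower the ratio. This test therefore does not decide the cause. H2-K1 and H2-D1 were called lower in Smarca1 KO and higher in DKO, while H2-T23 was called higher in both. A haplotype of another strain around the locus stays open: of 347 uncalled genes near Rps18, 21.6% had an unadjusted p under 0.05, against 18.5% elsewhere (two-sided Fisher's exact test, p = 0.143).

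Beta protocadherins fell in DKO against Smarca1 KO, and 3 explanations were weighed. Sharing of reads among beta genes is argued against by their summed counts, −1.272 (SE 0.118, adjusted p = 0.000671), with 0.34% of their 31-mers outside the beta cluster. For all clustered protocadherins the sum was 0.01 (SE 0.082, adjusted p = 0.972), which by the bound set beforehand speaks for shared reads, but it was set aside after the result was seen, since gamma genes, at 610.2 CPM in Smarca1 KO against 122.5 CPM for beta genes, dominate it, and the beta sum was then added. A haplotype around the cluster may still contribute: 4 of 93 neighbours within 5 Mb were called (4.3%, against 4.24% elsewhere; two-sided Fisher's exact test, p = 0.799), which does not decide it. Loss of Smarca5 also stays open, because the whole list was not called against WT (fry adjusted p = 0.491), while the beta sum was −0.52 against WT in DKO (adjusted p = 0.024) and 0.75 in Smarca1 KO (adjusted p = 0.0392).

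Zinc finger genes with the stem Zfp made up an outsized part of the falls: 50 of 372 fell and 2 rose in DKO against Smarca1 KO (13.4%, against 2.4% of other genes; adjusted p = 2.14e-19), 67 fell and 6 rose in DKO against WT, 43 fell in both, and 1 fell in Smarca1 KO against WT. A bias by GC content as the whole cause is argued against, because 90% of the 50 stayed called lower with GC-content offsets. Reads shared between paralogs as the whole cause are argued against by genes with under 5% shared 31-mers, where 16 of 248 Zfp genes fell (6.45%, against 2.21% of other such genes; two-sided Fisher's exact test, p = 0.000191, which counts genes as independent). For the 124 Zfp genes that share more, of which 34 fell, sharing may account for part, since their summed counts had a log2 fold change of −0.159 (SE 0.031, adjusted p = 0.0245). Loss of Smarca5 stays open. The 50 genes had a median of −0.66 in DKO against WT, but they were chosen as lower in the same DKO libraries, so this value decides nothing, and loss of Smarca5 and carriage of Cre cannot be told apart in this design.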
